A study of Mus musculus with 4 samples.

How the data were processed

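The series holds 4 expression arrays of total RNA from mouse skeletal muscle, with titles that code 2 samples as J and 2 as NJ at 0 h. The groups, replicate labels and time were read from the titles. Replicate labels are 1a and 1c for J and 1a and 1d for NJ, so only 1a occurs in both groups and no fit with replicate as a block was made.

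The deposited values are 1 intensity per probe set and array on a linear scale. The software and algorithm that made them are not given in the sources used here. The mean of each column after trimming 2% at each end lies between 800.5 and 800.6 in all 4 columns of deposited intensities, which shows scaling of each array to a common level. All values are above 0. Of the deposited columns, both titled 1a carry full digits and the other 2 are rounded to 1 decimal. This number format splits each group and was treated as a possible batch after the data were seen. It coincides with replicate label 1a against the other labels, so format and label cannot be told apart.

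The table has 12488 probe sets, of which 66 are controls that were left out of the tests. Probe sets were named through the platform's gene table. Of the other 12422, 10833 had 1 gene symbol, 396 had several and are not named here, and 1193 were not in that table and are unnamed here. Of the single symbols, 10817 had an entry in the RefSeq gene table of the assembly GRCm38.p6, 16 had none, and 0 were changed. No genome build is named for the array, so no coordinates are given.

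Intensities were taken as log2(value + 32). The medians of the 4 columns ranged from 8.29 to 8.67 on that scale, more than the 0.1 fixed beforehand as the limit, so the arrays were quantile normalised. The 9317 probe sets whose mean over all 4 arrays lay above the 25th percentile were kept. J and NJ were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 2 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05.

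For the 20 gene lists fixed before the data were examined, the probe set with the highest mean stood for each gene, which left 6774 genes. Where a gene had several probe sets they could disagree, as for Chrne, Nes, Ncam1 and Ank3. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether the genes of a list move one way on balance and makes no comparison with other genes. P-values of lists were adjusted over the 20 lists, and members were also adjusted over the list alone. The lists cover synaptic muscle transcripts, the dystrophin complex, the denervation response, fast and slow fibres, glycolysis, oxidative phosphorylation, ribosomal proteins, chaperones, immediate early genes, basement membrane, and markers of Schwann cells, neurons and axons, fibroblasts, endothelium, smooth muscle and pericytes, immune cells, satellite cells, blood and adipocytes.

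Genes are named by a rule fixed before the data were examined. It takes every measured member of the synaptic list. It takes 10 probe sets per direction among those that pass and do not overlap between groups, and where fewer pass, those with the smallest unadjusted p among probe sets above the median brightness whose groups do not overlap, at 1 probe set per gene. It also takes up to 4 members of each other list, those with the smallest unadjusted p, of which 4 are given for a list that passed and 2 for the rest. Genes named outside the rule are said to be so or serve only to give levels of a list.

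The alternatives fixed beforehand were the deposited scale, centring of each array on its median, pseudocounts of 1 and 100, no filter or a filter at the median, eBayes without the trend, leaving out each array in turn, the mean of all probe sets of a gene, and the other list tests. A number-format term in the fit and the synaptic list without Prkar1a and Nes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

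The scripts were tested on simulated data with means and spread modelled on the real data. Each of 20 simulations had 9317 probe sets and 200 changed ones. Without the number-format term, 5.07% of unchanged probe sets had an unadjusted p under 0.05 in limma. On the real arrays J against NJ gave 199 of 9317, against 466 expected by chance, and the split by number format gave 1118. The simulated errors thus did not match those of the arrays, and the recovery and false calls may not hold for them. Without the number-format term, limma at an adjusted p under 0.05 recovered 0% of changes of 1 on the log2 scale, 0.45% of changes of 2 and 8.67% of changes of 3, with 12 false calls over all simulations. With the term it recovered 6.63%, 41.8% and 78.0%, with 187 false calls over all simulations. A list shifted by 1 among 6774 genes was called in 20 of 20 simulations with the preset correlation and in 0 with the estimated one, and 0 of 400 tests of unshifted lists were called. Errors were drawn independently for each gene, so these counts do not give the false call rate for lists with correlated members. In the data the estimated correlation was 0.134 for the synaptic list and 0.103 for the fibroblast list. The number of arrays limits the precision of every value.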

Results

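Transcripts were measured in total RNA of mouse skeletal muscle on 4 arrays, each giving a signal for 12488 probe sets. The array titles carry the code J on 2 arrays (replicates 1a and 1c) and NJ on the other 2 (replicates 1a and 1d), all with a time of 0 h. The labels do not spell out the codes, which are used here as given. The series is titled for the neuromuscular junction, the synapse between a motor nerve and a muscle fibre, and the design sets J against NJ. Unless another scale is named, values are differences of J minus NJ on a log2(signal + 32) scale after quantile normalisation, with the standard error of the limma fit, over 2 arrays per group. This scale understates the change of dim genes. Nothing in the labels says that the arrays came from separate animals, so the spread between these samples may be technical. Standard errors and p-values do not measure that spread alone, since limma draws each variance toward a trend over all probe sets. Phldb2, for example, had standard deviations of 0.05 in J and 0.10 in NJ but a standard error of 0.66.

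Prkar1a, a regulatory subunit of protein kinase A, and Nes, the intermediate filament protein nestin, had higher signals on both J arrays than on both NJ arrays. Prkar1a had signals of 13636 and 14134 in J against 2145 and 3722 in NJ, a difference of 2.41 ± 0.39 or 5.30-fold, and it ranked first of all 9317 probe sets tested. Nes differed by 2.09 ± 0.45 or 4.26-fold at its brightest probe set and by −0.05 at a dimmer one, whose signals were 140 and 142 in J against 144 and 133 in NJ. Cadm1, a cell adhesion molecule, differed by 2.43 ± 0.42 and Phldb2, which encodes a phosphoinositide-binding protein also called LL5-beta, by 3.32 ± 0.66. Phldb2 had signals of 1484 and 1590 in J against 130 and 105.3 in NJ.

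No single probe set passed the test across all probe sets. With limma, 0 were higher and 0 lower in J at a Benjamini-Hochberg adjusted p under 0.05, the smallest adjusted p being 0.999. At an unadjusted p under 0.05, limma gave 117 higher and 82 lower, against 466 expected by chance alone. These counts were 259 and 296 with a term for the arrays' number format, described next, 302 and 580 without J 1c and 90 and 124 without J 1a, so neither their total nor their balance held. Both J values lay above both NJ values for 1266 probe sets and below them for 1196, together 26.4% of those tested, where chance gives 33.3%. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.

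The 2 arrays titled 1a carry full digits in the table and the other 2 are rounded to 1 decimal, so that each number format holds 1 J and 1 NJ array. A fit with a term for this number format, chosen after the data were seen, called 4 probe sets higher and 4 lower in J. With that term limma gave an adjusted p of 6.0e-06 for Prkar1a, 0.0012 for Cadm1, 0.0043 for Nes and 0.023 for Phldb2. The 4 lower ones were Ybx1, Tnnc2, Surf2 and Pxmp2, with limma adjusted p between 0.017 and 0.023. Of these, Ybx1, an RNA-binding protein, and Tnnc2, the troponin C of fast fibres, were named after their values were seen, and both were low mainly on array J 1c. Tnnc2 had a signal of 1301 there against 29568 to 145820 on the other arrays, and its difference was −0.07 between the 1a arrays and −4.28 between J 1c and NJ 1d. This fit leaves 1 residual degree of freedom, so its p-values rest largely on the variance trend over all probe sets. They do not measure how alike the differences of the number formats are. Phldb2, at 3.36 between the 1a arrays and 3.29 between J 1c and NJ 1d, had a larger adjusted p than Tnnc2. In 20 simulations with known changes the fit with the term gave 187 false calls, against 12 without the term. These are counts and not shares of the calls made, since the fit with the term also recovered more of the true changes. It recovered 41.8% of those of 2 on the log2 scale, against 0.45% without the term. The simulated errors did not match those of the arrays, so these values may not hold for the real data.

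Among the genes taken next by the naming rule, 6 more were higher on both J arrays, none of them past the test (limma adjusted p = 0.999 for each). Myl4, a myosin light chain of embryonic and atrial muscle, differed by 2.28 ± 0.56 at one probe set and 1.51 ± 0.48 at its brighter one. Lama2, the laminin alpha chain of the muscle fibre's basement membrane, differed by 1.56 ± 0.45. Irf8, a transcription factor of blood cells, differed by 2.56 ± 0.74, and Lsp1, an actin-binding protein of leukocytes, by 2.54 ± 0.77. Adipoq, the adipocyte hormone adiponectin, differed by 1.90 ± 0.59, and Trav9d-3, a T cell receptor segment, by 1.87 ± 0.51. Of the 10 genes taken in the other direction, Ndrg4 differed by −2.70 ± 0.76, the RIKEN transcript C030006K11Rik by −2.41 ± 0.74, Las1l by −2.27 ± 0.78 and Wdr55 by −2.23 ± 0.73. Ptprb, a receptor phosphatase of endothelium, differed by −2.16 ± 0.72, Pxmp2, a peroxisomal membrane protein, by −2.01 ± 0.63 and Surf2 by −2.01 ± 0.51. Bag2, a co-chaperone, differed by −1.44 ± 0.47, Txnrd3, a thioredoxin reductase, by −1.18 ± 0.37 and Lpl, lipoprotein lipase, by −1.19 ± 0.39.

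Genes of the muscle side of the synapse were split in direction, with a positive median. Of 29 such genes fixed before the data were examined, 22 had a probe set and 20 were bright enough to test, with 12 higher and 8 lower in J and a median difference of 0.31. The list passed limma's camera test with a preset correlation (adjusted p = 0.0069 over 20 lists). It did not pass with an estimated correlation (camera, adjusted p = 0.80) or in fry (adjusted p = 0.775). Prkar1a and Nes, its members with the smallest p, were also left out after the data were seen. The median was then 0.22 (camera at the preset correlation, adjusted p = 0.291). Taking out the strongest members was bound to weaken the list, so this shows only how far the call rests on them. In simulations, camera with an estimated correlation called a list shifted by 1 in 0 of 20. Not passing that test therefore decides little for the lists here, and fry was not simulated. Passing at the preset correlation of 0.01 is weak support too. A correlation of 0.134 was estimated for the synaptic list, and the simulated genes were independent. The list's median was 0.44 between the 1a arrays and 0.36 between J 1c and NJ 1d. Adjusted over the list alone, limma called 2 members higher (Prkar1a, adjusted p = 0.0027, and Nes, adjusted p = 0.010) and 0 lower, against 0 over all probe sets tested.

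Of the acetylcholine receptor subunits, Chrna1 differed by 2.36 ± 1.05, with signals of 515 and 1777 in J against 44.8 and 404 in NJ, and ranged from 0.93 to 3.79 with each array left out. Chrnd differed by 0.50 ± 0.75 and Chrnb1 by −0.21 ± 0.71. Chrne, the subunit of the adult receptor, differed by 0.20 ± 0.57 at its brightest probe set, which stands for the gene here, but by 2.80 ± 0.76 and 1.64 ± 0.79 at its other probe sets. Ache, the acetylcholinesterase that breaks down the transmitter, differed by 1.87 ± 0.77, and this came mostly from the 1a arrays (3.35, against 0.40 between J 1c and NJ 1d). Colq, which anchors that enzyme in the cleft, differed by −0.54 ± 0.69. Rapsn, the protein that clusters the receptors, differed by −0.16 ± 0.39 and Agrn, the clustering signal agrin, by −0.17 ± 0.90.

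Among the remaining members, Cd24a differed by 0.84 ± 0.42, the adhesion molecule Ncam1 by 0.81 ± 0.71 and Dtna, a dystrobrevin, by 0.78 ± 0.44, each with both J values above both NJ values at its brightest probe set. Another tested probe set of Ncam1 differed by −0.57, and by −1.68 between J 1c and NJ 1d. Lamb2, the synaptic laminin beta chain, differed by 0.43 ± 0.51, the transcription factor subunit Gabpa by 0.37 ± 0.82 and the glycosyltransferase B4galnt2 by 0.24 ± 0.88. Itga3, an integrin chain, differed by −0.68 ± 0.69, Erbb3, a neuregulin receptor, by −0.36 ± 0.93 and Utrn, utrophin, by −0.14 ± 0.83. Ank3 differed by −0.04 ± 0.43, and by 0.02 on the deposited scale, while its other probe set differed by 0.66. Other tested probe sets of Agrn and Itga3 differed by −0.62 and −0.71. Musk and Sntb2 had probe sets that were too dim to test, and the other 7 genes of the list had no probe set named for them here.

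**Figure D1:**
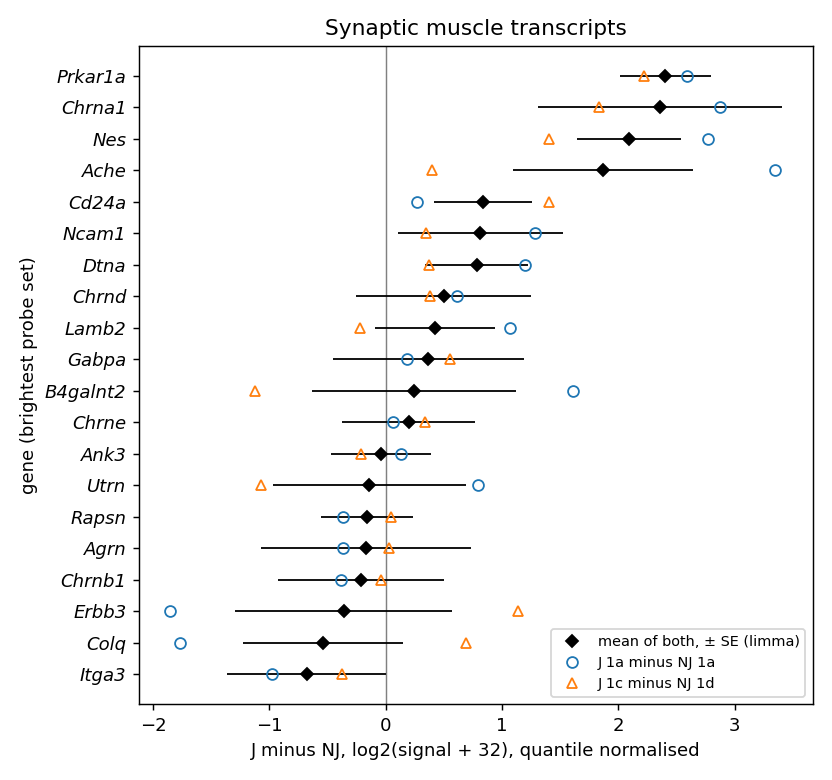
J minus NJ of the 20 tested genes of the synaptic list, each at its brightest probe set (x axis, difference of quantile normalised log2(signal + 32) values). Diamonds are the mean difference and bars the standard error of the limma fit over 2 arrays per group, circles the difference between the 1a arrays and triangles that between J 1c and NJ 1d; Prkar1a, Chrna1, Nes and Ache have the highest means, from 2.41 to 1.87.

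The call of the synaptic list was lost without array NJ 1a (median 0.08, camera adjusted p = 0.123) and without J 1c (0.24, 0.318), while the median was 0.63 without J 1a and 0.62 without NJ 1d. It was also lost without the intensity trend in the variance prior (camera adjusted p = 0.064).

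The fibroblast list, markers of connective tissue cells, was the other list that passed, with 15 of 21 members higher in J, 6 lower and a median of 0.34 (camera, adjusted p = 0.031). It did not pass with an estimated correlation (camera, adjusted p = 0.80) or in fry (adjusted p = 0.775). Postn, the matrix protein periostin, differed by 3.43 ± 0.81 and was the member that passed when adjusted over the list alone (limma, adjusted p = 0.040), against 0 over all probe sets. Col6a1, a collagen VI chain, differed by 1.03 ± 0.39 and Timp1, an inhibitor of matrix proteases, by 1.16 ± 0.68, while Serpinf1 differed by −1.33 ± 0.57. The difference of Timp1 was 2.45 between the 1a arrays and −0.13 between J 1c and NJ 1d, and ranged from 0.28 to 2.04 with each array left out. The fibrillar collagens Col1a1 and Col3a1 differed by 0.67 ± 0.44 and −0.24 ± 0.52. The list's median was 0.46 between the 1a arrays and 0.17 between J 1c and NJ 1d. Its call was lost without J 1a (median 0.16, camera adjusted p = 0.535), without NJ 1d (0.21, 0.443), with median centring (0.23, 0.052), with the filter at the median (0.32, 0.085) and without the intensity trend (camera adjusted p = 0.086), and the median was 0.56 without J 1c.

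The other 18 lists did not pass camera, the lowest adjusted p being 0.240, and no member of any of them passed limma when adjusted over the list alone. Fast fibre genes had 5 members higher and 10 lower in J, with a median of −0.17. Actn3, the alpha-actinin of fast fibres, differed by −1.18 ± 0.69 and Tpm1, a tropomyosin, by −1.11 ± 0.53. The difference of Actn3 was −0.16 between the 1a arrays and −2.21 between J 1c and NJ 1d, and ranged from −2.29 to −0.08 with each array left out. With the preset correlation this list did pass camera on the deposited scale (median −0.61, adjusted p = 0.0056), with median centring (−0.68, 0.0048), with the number-format term (adjusted p = 0.024) and without J 1a (−0.14, 5.0e-04), and its median was −0.07 without J 1c. With an estimated correlation its camera adjusted p was 0.80 in the main setting, 0.894 on the deposited scale, 0.85 with median centring, 0.964 with the term and 0.84 without J 1a, and fry with the term gave an adjusted p of 0.857. All 15 fast fibre members were lower on J 1c than the mean of the other 3 arrays on the deposited scale.

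Genes of oxidative phosphorylation, the respiratory chain of mitochondria, had 22 members higher and 44 lower, with a median of −0.13 (camera, adjusted p = 0.296). This median was −0.04 without NJ 1d, −0.07 without J 1c, −0.09 without J 1a and −0.22 without NJ 1a. Uqcrc2 differed by −0.88 ± 0.49 and Cox7a2l by −0.65 ± 0.36. The list passed camera on the deposited scale (median −0.28, adjusted p = 0.0019) and with median centring (−0.34, 0.0036), but not with an estimated correlation (camera, adjusted p = 0.894 and 0.85). Slow fibre genes had 7 members higher and 4 lower, with a median of 0.06 and −0.01 with median centring. Myh7, the slow myosin heavy chain, differed by −1.13 ± 0.95 and Fabp3 by −0.52 ± 0.39. Glycolysis genes had 6 higher and 9 lower, with a median of −0.06. Pygm, the muscle glycogen phosphorylase, differed by 0.97 ± 0.40. Tpi1, triose phosphate isomerase, differed by 0.74 ± 0.55, and by −0.11 on the deposited scale and −0.17 with median centring.

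In the dystrophin complex 5 members were higher and 6 lower, with a median of −0.21. Its members included Lama2 and Sgce, an epsilon sarcoglycan that differed by 1.02 ± 0.72. The denervation list, genes that muscle raises when its nerve is lost, had 6 members higher and 3 lower, with a median of 0.36 (camera, adjusted p = 0.296) that ranged from 0.17 to 0.56 with each array left out. Ankrd1 differed by 1.92 ± 0.83, from 0.54 to 3.30 with each array left out, and Myl4, at its brightest probe set, by 1.51 ± 0.48. Basement membrane genes had 8 higher and 5 lower, with a median of 0.21. Col18a1, a collagen of basement membranes, differed by 1.61 ± 0.64 and Lama5 by 1.46 ± 0.81, the latter with 2.76 between the 1a arrays and 0.15 between J 1c and NJ 1d (0.50 to 2.41 with each array left out). Chaperones had 7 higher and 11 lower (median −0.08), with Hspa9, the mitochondrial HSP70, at −1.09 ± 0.38 and Hspb8 at 0.80 ± 0.38. Immediate early genes had 10 higher and 6 lower (median 0.12), with Egr2 at 1.11 ± 0.84 (0.07 to 2.16 with each array left out) and Zfp36 at −1.04 ± 0.81 (−1.69 to −0.38). Of 78 ribosomal protein genes 30 were measured, 13 of them higher and 17 lower (median −0.09), with Rpl41 at −0.98 ± 0.69 and Rpl35a at −1.02 ± 0.75.

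Markers of other cell types gave no further call. Neuron and axon genes had 5 higher and 6 lower, with a median of −0.0007 and 0.06 on the deposited scale. Uchl1 differed by 1.60 ± 0.94 and Snap25, a protein of the nerve terminal, by 1.70 ± 1.07. With each array left out Uchl1 ranged from 0.34 to 2.86 and Snap25 from 0.01 to 3.38, and Snap25 differed by 3.34 between the 1a arrays and 0.05 between J 1c and NJ 1d. Schwann cell genes had 4 higher and 7 lower, with a median of −0.24. Apod differed by 2.09 ± 0.84 and S100b by −1.18 ± 0.81. Smooth muscle and pericyte genes had 9 higher and 2 lower, with a median of 0.41 (camera, adjusted p = 0.296), Acta2 at 0.56 ± 0.52 and Mylk at 0.42 ± 0.38. This list passed without NJ 1a (median 0.43, camera adjusted p = 0.0092; with an estimated correlation, adjusted p = 0.835), and its median was −0.08 without J 1a and −0.17 without NJ 1d. Endothelial genes had 4 higher and 8 lower (median −0.18), with Vwf at 1.87 ± 0.72 and Kdr at −1.40 ± 0.96. Vwf differed by 3.24 between the 1a arrays and 0.51 between J 1c and NJ 1d, and ranged from 0.97 to 2.78 with each array left out. Immune cell genes had 11 higher and 7 lower (median 0.05), with S100a8 at 2.09 ± 0.75 and Fcer1g at −2.55 ± 0.82. Satellite cell genes had 4 higher and 2 lower (median 0.11), with Sdc3 at −0.97 ± 0.82 and Itga7 at 0.41 ± 0.42. Adipocyte genes had 3 higher and 4 lower (median −0.05), with Adipoq at 1.90 ± 0.59 and Lpl at −0.96 ± 0.43 at its brightest probe set. The 5 blood genes had 4 higher and 1 lower, with a median of 0.06, −0.0045 on the deposited scale and −0.07 with median centring, and Bpgm at −0.60 ± 0.46 and Alas2 at 0.58 ± 0.71.

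Of the 76 differences of named genes or probe sets, 44 moved by more than 1.5 times or changed sign when an array was left out. Among those that kept their sign and are not given above, the ranges were 0.88 to 2.86 for Ache, 0.21 to 1.42 for Ncam1, 0.38 to 1.30 for Cd24a, 0.49 to 1.08 for Dtna, 1.63 to 3.45 for Lsp1, −2.997 to −1.03 for Pxmp2 and −2.91 to −1.42 for Ptprb. They were 0.55 to 1.48 for Sgce, −0.88 to −0.16 for Fabp3, 0.06 to 1.42 for Tpi1, −1.29 to −0.48 for Uqcrc2, 0.52 to 1.07 for Hspb8, 1.35 to 2.83 for Apod and −1.77 to −0.59 for S100b. For Sdc3 the range was −1.76 to −0.17, for Itga7 0.05 to 0.76, for Bpgm −1.15 to −0.05 and for the brightest probe set of Lpl −1.37 to −0.55.

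The mean over a list's members had the opposite sign to its median for the dystrophin complex, slow fibre, glycolysis, Schwann cell, neuron and axon, immune cell, satellite cell and adipocyte lists. Camera's direction followed the mean in these lists except that of satellite cell genes, where it followed the median.

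**Figure D2:**
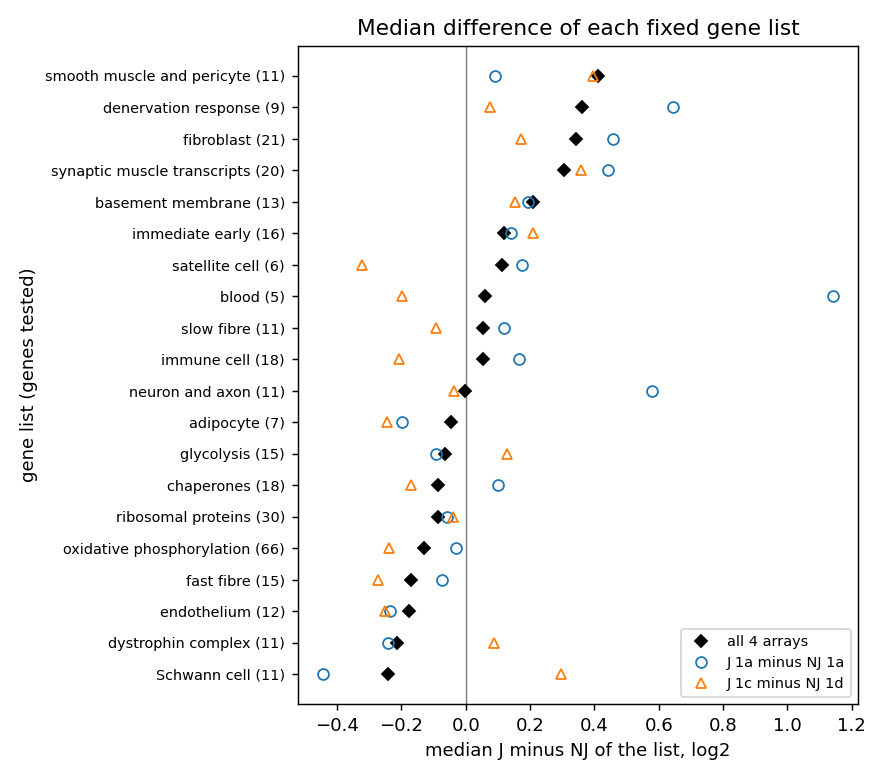
Median difference J minus NJ of the 20 gene lists (x axis, log2 units; numbers of genes tested in brackets), over all 4 arrays (diamonds), between the 1a arrays (circles) and between J 1c and NJ 1d (triangles). The 2 lists that passed camera at the preset correlation, synaptic muscle transcripts and fibroblast, have medians of 0.31 and 0.34 over all arrays and lie above 0 within both number formats.

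The arrays did not group by code. Across probe sets, which are not independent replicates, log2 signals of J 1c and NJ 1d had a Pearson correlation of 0.926, those of J 1a and NJ 1a 0.823, those of J 1a and J 1c 0.815, those of J 1a and NJ 1d 0.818, those of NJ 1a and J 1c 0.864 and those of NJ 1a and NJ 1d 0.865, so that J 1a had the lowest values with every other array. The mean correlation was 0.840 within groups and 0.858 between them. The differences J minus NJ of the 2 number formats had a correlation of 0.0016 across the probe sets tested.

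Array J 1c stood apart in its brightest signals. Its highest signal was 41086, against 125530 to 238290 on the other arrays, and the geometric mean of its 9 bacterial control probe sets was 5354 against 23064 to 42829. The control probe sets for Gapdh, which read the ends of the transcript, gave a ratio of the 3′ end to the 5′ end of 1.43 on J 1c, 7.61 on J 1a, 8.34 on NJ 1a and 7.48 on NJ 1d. The 3′ signal was 22552 on J 1c against 87950 to 192920 on the other arrays, and the 5′ signal 15802 against 11760 to 25364. The low ratio thus came from a low 3′ signal and cannot be read as more intact RNA. For Actb the ratios were 4.61, 5.46, 4.75 and 8.46 in the same order. Median signals were 376 on J 1a, 367 on NJ 1a, 300.2 on J 1c and 280.5 on NJ 1d.

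**Figure D3:**
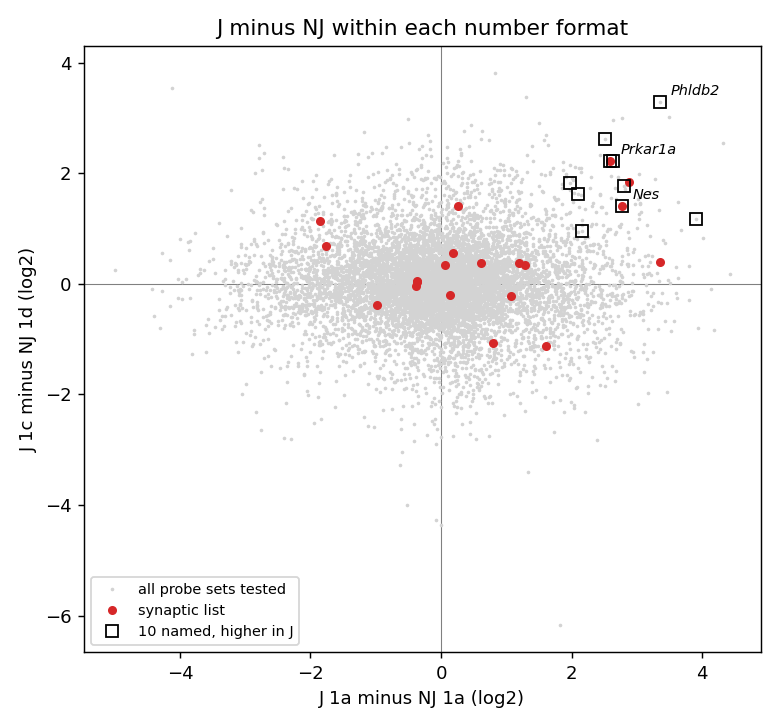
Difference J minus NJ between the 1a arrays (x axis) against that between J 1c and NJ 1d (y axis) for the 9317 probe sets tested, in log2 units. Grey points are all probe sets, red points the 20 genes of the synaptic list and squares the 10 named genes higher in J; over all probe sets the correlation is 0.0016, and Phldb2, Prkar1a and Nes lie high on both axes.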

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

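The number-format term and the synaptic list without Prkar1a and Nes were chosen after the data were seen, and all other alternatives before. No analysis paired by replicate label was possible because the groups share only label 1a. The number-format term sets J 1a with NJ 1a and J 1c with NJ 1d. It therefore cannot be told apart from a block of label 1a against the other labels. Where an array was left out its group has 1 array, which limma assumes to vary like the other group. The count of probe sets past the threshold was 0 in each direction under every alternative except the number-format term, which called 4 higher and 4 lower, with 1 residual degree of freedom. At an unadjusted p under 0.05, limma gave 117 higher and 82 lower as reported, 259 and 296 with that term, 170 and 128 without the filter and 56 and 46 with the filter at the median, which test more and fewer probe sets. Without J 1a the counts were 90 and 124, without J 1c 302 and 580, without NJ 1a 75 and 30, and without NJ 1d 162 and 57. Under the alternatives the median difference of all probe sets stayed between −0.04 and 0.02. For the named genes, 868 of 900 values under alternatives kept their sign and their side of the threshold, 26 changed sign and 6 passed, all 6 with the number-format term. Of 285 values of the lists other than the synaptic one, 37 changed sign, 7 lost the call, all of the fibroblast list, and 7 gained one. The arrays are few and many probe sets are dim, so that differences of dim genes rest on the pseudocount and the filter. Apart from the numbers of probe sets tested, the cause of these changes was not tested.

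The synaptic list kept a positive median under every alternative. Its camera call with the preset correlation held on the deposited scale, with median centring, with both pseudocounts, without the filter or with the stricter one, with the mean of all probe sets, with the number-format term, without J 1a and without NJ 1d. With an estimated correlation or in fry no list passed in any setting, the lowest adjusted p being 0.769 and 0.175. The estimated correlation decides little here, since it called a list shifted by 1 in 0 of 20 simulations. The preset correlation of 0.01 lies below the 0.134 and 0.103 estimated for the synaptic and fibroblast lists, so calls made with it are weak support. With the number-format term the synaptic, fibroblast and fast fibre lists each had an adjusted p of 0.964 with an estimated correlation (camera) and 0.857 in fry. The synaptic median of 0.306 was unchanged but did not pass without the intensity trend (camera adjusted p = 0.064), with an estimated correlation (adjusted p = 0.80) and in fry (adjusted p = 0.775). Without Prkar1a and Nes it was 0.222 (adjusted p = 0.291). With each array left out it lay between 0.083, without NJ 1a (camera adjusted p = 0.123), and 0.627, without J 1a (5.0e-04), and it was 0.245 without J 1c (0.318). Its adjusted p ranged from 5.0e-04 to 0.318 for camera with the preset correlation over its alternatives.

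Of the lists, the dystrophin complex had a median of 0.247 with the filter at the median, and slow fibre genes −0.012 with median centring. The median of neuron and axon genes was 0.058 on the deposited scale, 0.221 without the filter and 0.215 with the mean of all probe sets of a gene. With that mean endothelial genes had 0.083 and adipocyte genes 0.082, and adipocyte genes had 0.095 with a pseudocount of 100 and 0.118 without the filter. Blood genes had −0.0045 on the deposited scale and −0.066 with median centring. None of these lists passed camera in those settings.

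With each array left out in turn, list medians ranged from −0.142 to 0.102 (dystrophin complex), −0.033 to 0.110 (slow fibre), −0.250 to 0.124 (glycolysis), −0.175 to 0.076 (ribosomal proteins), −0.107 to 0.051 (chaperones), −0.332 to 0.311 (immediate early) and −0.636 to 0.257 (Schwann cell). The ranges were −0.197 to 0.235 (neuron and axon), −0.269 to 0.171 (endothelium), −0.172 to 0.696 (smooth muscle and pericyte), −0.314 to 0.206 (immune cell), −0.239 to 0.278 (satellite cell), −0.278 to 0.805 (blood) and −0.354 to 0.150 (adipocyte).

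Ank3 differed by 0.018 on the deposited scale, and Tpi1 by −0.106 there and −0.167 with median centring. With each array left out, the difference ranged from −1.125 to 0.706 for Chrnb1, −0.146 to 0.548 for Chrne, −0.335 to 0.012 for Rapsn, −1.229 to 0.155 for Colq, −0.820 to 0.544 for Utrn, −0.0083 to 0.859 for Lamb2 and −1.695 to 0.975 for Erbb3. It ranged from −0.644 to 1.132 for B4galnt2, −0.384 to 1.122 for Gabpa, −0.132 to 0.057 for Ank3 and −1.070 to 0.736 for Agrn. Outside the synaptic list it ranged from −2.329 to 0.064 for Myh7, −2.102 to 0.134 for Rpl41, −3.106 to 0.302 for Kdr, −0.172 to 1.291 for Acta2 and −0.072 to 1.237 for Alas2.

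The mean correlation of arrays within groups was 0.799 with Spearman's coefficient and 0.786 over the brighter probe sets. In each case it stayed below that between groups, 0.819 with either choice.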

Other observations

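The tests of the fibroblast list without array J 1a and of the count of probe sets lower by 4-fold were written before their results were seen. The limma, camera and fry tests of J against NJ over all 4 arrays, with the full lists, were also fixed beforehand. All other tests in this part were chosen afterwards.

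Some transcripts outside the naming rule, picked after their values were seen, differed at least 4-fold in the same direction within both number formats. Gpm6b, a membrane glycoprotein best known from neurons and glia, had signals of 577 and 466 in J against 23.8 and 22.5 in NJ. Also higher were Postn, Phldb2, Irf8, Cadm1, Prkar1a, a dimmer probe set of Chrne, S100a8, the embryonic globin Hbb-y, Tmpo, a protein of the nuclear lamina, the potassium channel subunit Kcnab3, Faap20 and a probe set unnamed here. Lower were Ndrg4, Las1l, Gfra1, a receptor for glial cell line-derived neurotrophic factor, the immune genes Cd48 and Fcer1g, Frat1 and Evl. There were 13 probe sets higher, against a mean of 7.23 and a middle 95% of 2 to 13 when the differences of one format were shuffled among probe sets of like brightness in 1000 draws (one-sided permutation p = 0.030). There were 7 lower, against a mean of 5.58 and a middle 95% of 2 to 10 (one-sided permutation p = 0.322), so both counts lie within what shuffling gives, the higher one at its upper bound (p = 0.027 over 20000 further draws).

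Of the 3 ways to split the 4 arrays into 2 and 2, J against NJ gave 199 probe sets at an unadjusted p under 0.05 in limma, the number formats gave 1118 and the third split 172, with 0 past the adjusted threshold in each. The count for the number formats points to a structure of the arrays apart from the codes, and the correlations grouped by format only in part. The highest was 0.926, between J 1c and NJ 1d, and J 1a had 0.823 with NJ 1a against 0.815 with J 1c and 0.818 with NJ 1d. NJ 1a went the other way, with 0.823 with J 1a, 0.864 with J 1c and 0.865 with NJ 1d. The number of lists past camera was 2 for J against NJ and 0 for the other splits. The synaptic list's median was nonetheless larger in size between the formats. It was −0.38 for full digits minus rounded (camera adjusted p = 0.166), 0.31 for J minus NJ and 0.14 for the third split. These splits are too few for a share under 0.05.

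The synaptic list had a median above 0 and passed camera at the preset correlation only. It did not pass with an estimated correlation (camera, adjusted p = 0.80) or in fry (adjusted p = 0.775). The preset call rested on Prkar1a and Nes, its members with the smallest p (camera adjusted p = 0.291 without them). A junction-enriched sample may give such a pattern if J stood for junctional, which the labels do not say and which was not tested. An additive difference between number formats cancels in J minus NJ by the design, so the smaller of the list's within-format medians, 0.357, does not test it, and other differences between the formats stay open. Nerve and Schwann cell RNA in the J samples may add to the pattern and cannot be told apart from it: the mean difference was 0.53 for the synaptic list and 0.19 for the 22 nerve and Schwann cell genes, a gap of 0.336 (two-sided permutation p = 0.237, genes taken as units). Abundant members of those lists were mixed, with Mbp at −0.53, Mag at 0.38, Tubb3 at −0.01 and Stmn2 at −0.16, and Egr2 is also in the immediate early list.

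The fibroblast list had a median of 0.34 and passed camera at the preset correlation only, not with an estimated correlation (adjusted p = 0.80) or in fry (adjusted p = 0.775). A lower share of muscle fibre in the J samples, which would raise every other cell type alike, cannot be told apart from a change in fibroblast transcripts: the gap to the mean of the 81 members of the other cell type lists (0.08) was 0.321 (two-sided permutation p = 0.098, genes taken as units). The most abundant non-fibroblast markers do not settle it, since muscle expresses several of them, such as Car3 (a difference of 0.14), which the slow fibre list also holds. Array J 1a alone stays a candidate cause too, since without it the median was 0.156, still above 0, and the camera call was lost. The call was also lost without NJ 1d (median 0.214), so that loss is not particular to J 1a.

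Fast fibre transcripts were low on array J 1c on the deposited scale, and no biological explanation was tested. For 4 members among the brightest 1% that other probe sets match in brightness (Casq1, Pvalb, Ckm and Ryr1), the median log2 deficit against the mean of the other 3 arrays was −0.995, inside the middle 95% of matched sets (−1.72 to −0.62), which is consistent with a compressed top of the signal range on that array. For the 3 dimmer members (Tnni2, Mylpf and Tpm1) it was −0.288, within a matched range that spans 0 (−0.72 to 0.64), so nothing can be told there. The 9 probe sets outside the muscle lists that were at least as bright as Tnnc2 on the other arrays had a median deficit of −2.11, and the other 7 members had −2.44, inside the middle 95% of random sets of those 9 (−3.47 to −1.44), which is consistent with a compressed top, though 9 are few and Myh4, Actn3 and Atp2a1 read below most of the 30 brightest probe sets that were dimmer than Tnnc2. Tnnc2 itself, at −5.91, lay below all 9 (lowest −3.78), and its signal of 1301 on J 1c lay below all of those 30 (lowest 8842), so a compressed top alone does not give its value and its cause stays open.

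The 100 probe sets brightest on the other 3 arrays, a choice that favours a deficit on the array left aside, included 75 outside the muscle lists, with a median difference on J 1c of −0.95 and 97.3% of them lower there. The same choice with another array left aside gave medians of 0.08 (J 1a), 0.12 (NJ 1a) and 0.35 (NJ 1d). Over all probe sets the median on J 1c was −0.09, and for the bacterial controls it was −2.30.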
